A study of Bifidobacterium breve UCC2003 with 2 samples.

How the data were processed

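Bifidobacterium breve UCC2003 was grown without oxygen to an OD600 of 0.5 in a modified MRS medium that held cysteine at 0.05% and either purified GOS or ribose at 1% (both weight per volume), per the labels' protocols. Total RNA of both cultures of a replicate was labelled with Cy3 and Cy5 and hybridised to 1 two-colour Agilent array. There were 2 such arrays with opposite dyes, which the labels call biological replicates 1 and 2. Both arrays were scanned from 1 slide, so no batch could be separated.

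Scans were converted to spot values with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner tables hold, for each spot and channel, the mean signal intensity and the median local background intensity, neither of them normalized, per the file headers. They also hold the software's processed signal intensity, which is background-subtracted, spatially detrended and dye-normalized, per the file headers; the dye normalization method is not given in the sources used here. Flags for spots well above background, saturated or non-uniform are other deposited columns with values of 0 or 1. The deposited value table holds log10 ratios of Cy5 over Cy3. Its values differed from the scanner software's own log10 ratio on 0 of 10807 spots per array, at a tolerance of 1e-09. It was therefore not turned for the dye swap, and its median was 0 on both arrays. Spots with a surrogate in both channels, 2291 on replicate 1 and 1797 on replicate 2, are listed there at a ratio of 0.

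Each array held 10263 spots that were not controls, for 5664 probes of 60 bases, of which 4599 were spotted 2 times. Each of 1888 features had 3 probes. Of these, 1864 were chromosomal (1843 locus tags, 20 tRNA features and 1 for 16S rRNA), and the other 24 (7 spike features and 17 plasmid or unplaced ones) were left out of the tests. The 3 probes of a gene mostly overlapped: their start positions, as the probe names give them, spanned a median of 7 bases, and under 60 bases in 1403 features. They are thus repeated readings of 1 place in the transcript. No spot was saturated. The median signal lay between 476 and 677 per channel, against 277 to 386 for the 79 negative control spots and 33 to 36 for the local background. Local background thus understates the signal of a spot without target, and ratios of dim genes are drawn towards 1.

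Mean signals were background-corrected with normexp (offset 50), and each array was normalized by loess with a span of 0.3 and weight 0 for control and spike spots, in limma 3.58.1 under R 4.3.3. Spots flagged as non-uniform were dropped, spots of a probe averaged, and probes of a gene averaged on the log2 scale. The sign was turned on the array with GOS in Cy3. The median SD between the probes of a gene was 0.04 on the log2 scale. A gene was tested if at least 1 probe was well above background in at least 1 channel on both arrays, which held for 1319 genes and not for 545. A probe counted as well above background if the flag was set on a share of at least 0.5 of its spots. The turned ratios were tested against 0 with lmFit and eBayes, with 1 residual and 25.8 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. A dye effect cancels in the mean of the swapped arrays and stays in the residual. With so few arrays the variance of a gene comes mostly from the prior, and each array alone gives a value with no test.

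Where a gene was not well above background in the channel of 1 sugar on both arrays, a bound was given. It sets the bright sugar's mean log2 signal against the mean of, per array, the lowest signal among probes well above background in that channel or the gene's own, whichever was higher. Signals per channel were taken after loess and Aquantile normalization. Of the genes called, 9 higher and 21 lower ones had only a bound. A bound is an estimate from the mean of both arrays under the main processing and carries no error. Other processing, or 1 array alone, can give folds below it.

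The regularised test of Cyber-T, named for the study, was rebuilt with a window of 101 genes and a prior weight of 10, both chosen here because its settings are not given in the sources used here. Gene lists of at least 3 measured genes were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and by ranks. Of the 24 lists fixed before the data were examined, the 3 given by locus tag could be used. The other 21 were defined by words in gene names or products and could not be run: the array names genes by locus tag alone, and 0 of these tags were found among the 2016 genes of the reference table, which is of another strain (assembly ASM102517v1). For the same reason the rule for named genes was shortened. It took the 16 genes with the largest rise and the 12 with the largest fall, among those past the threshold and changed the same way on both arrays, with all members of the 3 clusters. Named are 11 cluster members, 10 of which are also among the 16, and the 2 genes with the largest mean change in either direction outside them; the other members are counted with their lists but not reported here one by one. The other 2 genes that rose had log2 ratios of 1.42 to 1.53, and the other 10 that fell had ratios of -6.34 to -1.00.

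The steps from spot signals to calls were tested on simulated data: spot signals of the 1319 genes on 2 arrays, with 200 genes changed by known folds. limma called 25 of 50 genes changed 1.5-fold, 48 of 50 changed 2-fold, 50 of 50 changed 3-fold and 50 of 50 changed 8-fold, each with the true sign. It called 0 of 1119 unchanged genes, as did the Cyber-T test, which called 21 of the 50 genes changed 1.5-fold. The simulation used the same noise level for all genes and had 6.4 prior degrees of freedom, against 25.8 in the data. Its limma test was thus stricter, and its 0 false calls do not carry over to the calls made here. Estimated changes were too small, with a median absolute log2 ratio of 2.24 for a true value of 3, since the simulated spots carried the signal of the negative controls. Camera gave a p under 0.05 to 0% of 500 random lists of unchanged genes. The simulated noise was independent between genes, and the changed genes stayed among those the lists were set against. This share therefore does not check the preset correlation.

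Alternatives covered the background correction, the normalization, the filter on dim genes, the summary over probes, the test, the deposited value table, and each array alone. Leaving out the genes whose probes have the same sequence as those of another gene was added after the data had been seen.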

Results

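The transcriptome of Bifidobacterium breve UCC2003, a bifidobacterial strain from the infant gut, was compared between cells grown on galacto-oligosaccharides and cells grown on ribose as the sole carbon source. Galacto-oligosaccharides (GOS) are short chains of galactose, mostly ending in glucose, and the preparation used here was a purified one. Ribose is a pentose and served as the reference sugar. The study set out to find the genes with which this strain takes up and uses GOS. RNA from each pair of cultures was hybridised to 1 two-colour array, and there were 2 arrays, which the labels give as biological replicates 1 and 2. On replicate 1 the GOS sample carried Cy3 and the ribose sample Cy5, and on replicate 2 the dyes were swapped. All ratios below are GOS over ribose, and every error is the spread between these 2 arrays (n = 2), whose small number limits the precision. The array carried 3 probes of 60 bases for each of 1864 chromosomal features, of which 1843 were named by locus tag. A total of 1319 of them were well above background in at least 1 channel on both arrays and were tested. On replicate 1, 58.7% of the spots were well above background in the GOS channel and 59.1% in the ribose channel. On replicate 2 these shares were 58.7% for GOS and 71.5% for ribose.

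Growth on GOS went with higher transcript levels of 3 gene clusters described in this strain for the uptake and breakdown of galactose-containing sugars. Because the study characterised them on these samples, their rise is not independent evidence. By probes of their own, 4 of the 6 genes of the gal cluster, 3 of the 5 of the gos cluster and both genes of the lac cluster rose. The other 2 genes of gal and 2 of gos were read by probes that both clusters share, and those probes rose too. Growth on ribose went with far higher levels of 1 run of 5 consecutive locus tags, whose mean log2 ratios lay between -6.81 and -5.65. On GOS these genes were at or near background, so that the size of their change is uncertain: 4 of the 5 were well above background on GOS on 1 of 2 arrays. The remaining 1 was so on neither array and was at least 56.5-fold higher on ribose under the main processing. Other processing, or 1 array alone, can give folds below such a bound. In total 105 genes were higher and 131 lower on GOS at a Benjamini-Hochberg adjusted p under 0.05 in limma, or 17.9% of the genes tested. Most of these differences were small. Among the genes called, 26 were over 2-fold higher and 11 over 2-fold lower, whereas 140 differed by 1.5-fold or less. Over the tested genes the log2 ratios of both arrays correlated at r = 0.906 (Spearman rho 0.568), and at r = 0.697 over the 1299 genes under 3-fold. These are correlations across genes, which are not independent replicates.

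**Figure D1:**
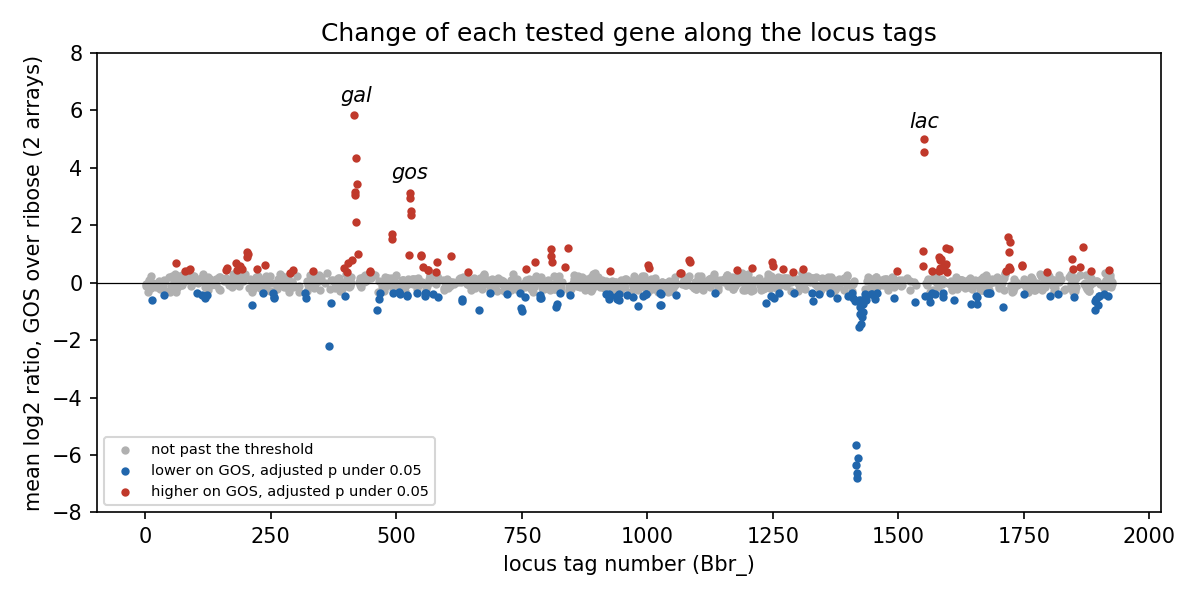
Mean log2 ratio of GOS over ribose (vertical axis, 2 arrays) for each tested gene with a locus tag, placed by the number of its tag (horizontal axis); red and blue points passed the test in either direction and grey points did not. Most genes of the gal, gos and lac clusters stand above 2, Bbr_0526 lies at 0.97 among other genes that rose, and 5 consecutive tags lie between -6.81 and -5.65, values that rest on a GOS signal at or near background.

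The gal cluster has been described in this strain as a galactan and galacto-oligosaccharide locus. It holds, among others, the transporter genes galC and galD, the beta-galactosidase gene galG, the LacI-type regulator gene galR and the endogalactanase gene galA. These names are background from published descriptions, because the files give locus tags alone. All 4 members with probes of their own rose, and the same 4 passed when adjusted over the list alone. Bbr_0417 (galC), the solute-binding protein gene, was at least 50.7-fold higher on GOS (adjusted p = 5.98e-24, SD of the log2 ratio 0.34). Bbr_0420 (galG) was at least 16.9-fold higher (adjusted p = 7.97e-22) and Bbr_0422 (galA) at least 10.2-fold higher (adjusted p = 1.70e-19). These 3 genes were not well above background on ribose on either array, so that only a lower bound under the main processing can be given. Without background correction the log2 ratios of Bbr_0417, Bbr_0420 and Bbr_0422 were 5.05, 3.53 and 2.73, which are folds below these bounds. With the deposited log ratios they were 8.16, 6.64 and 5.50. Bbr_0421 (galR) was detected on both sugars and was 4.37-fold higher, a log2 ratio of 2.13 ± 0.23 (SD, adjusted p = 2.59e-14).

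In the gos cluster (Bbr_0526 to Bbr_0530) all 3 members with probes of their own rose, and the same 3 passed when adjusted over the list alone. Bbr_0529 had a log2 ratio of 2.50 ± 0.26 (SD), or 5.65-fold, and Bbr_0530 one of 2.37 ± 0.26, or 5.17-fold. Bbr_0526 was at least 1.65-fold higher (adjusted p = 4.11e-07) and was not well above background on ribose. Its log2 ratio of 0.97 moved to 0.60, a fold below that bound, without background correction and to 2.42 with the deposited log ratios. Of the lac cluster, Bbr_1552 (lacZ6, a beta-galactosidase gene) was at least 21.1-fold higher and Bbr_1551 (lacS, a lactose permease gene) at least 15.6-fold higher. Neither was well above background on ribose, so that these are lower bounds under the main processing. Without background correction both genes had folds below these bounds, and with the deposited log ratios both had folds above them. The adjusted p-values of Bbr_1552 and Bbr_1551 were 3.80e-23 and 6.92e-22, and both genes passed when adjusted over the list alone.

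For 2 genes of the gal cluster and 2 of the gos cluster the probes could not tell the clusters apart. For example, all 3 probes of Bbr_0418 (galD) had the same sequences as the 3 probes of Bbr_0527. Their log2 ratios were accordingly alike, at 3.05 ± 0.38 (SD) for Bbr_0418 and 2.97 ± 0.45 for Bbr_0527. Which of the paired genes carried the rise is therefore uncertain.

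**Figure D2:**
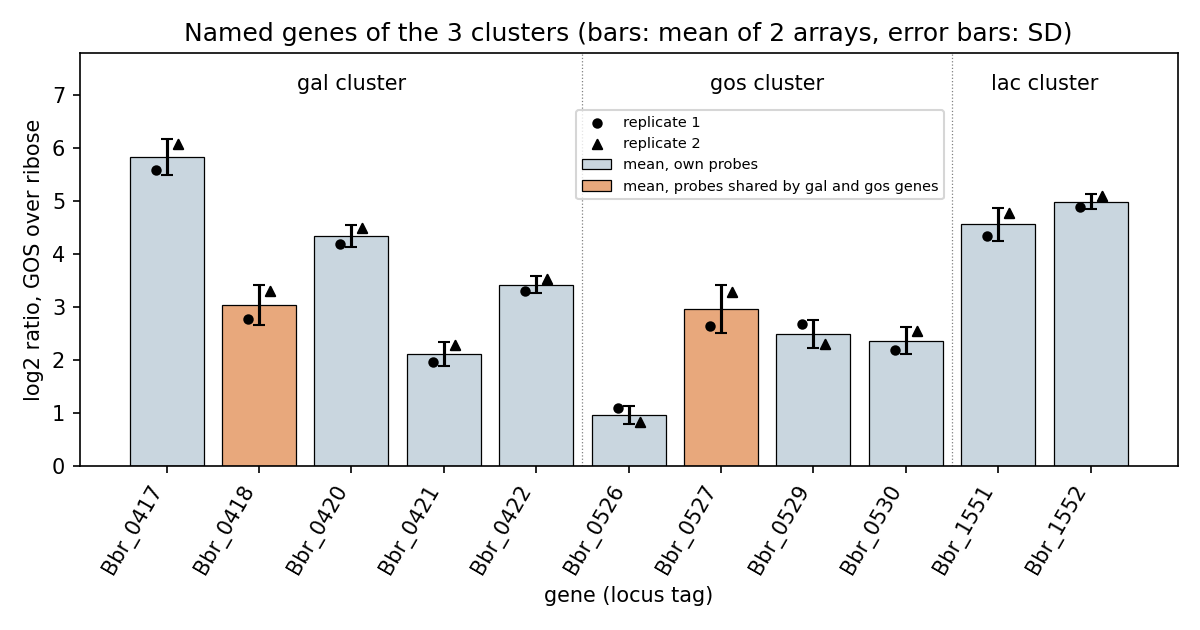
Log2 ratio of GOS over ribose (vertical axis) for 11 genes of the gal, gos and lac clusters; bars are means of 2 arrays, error bars are SD, and points are the single arrays. All bars lie above 0, and the 2 orange bars belong to genes whose probes are shared; the values of Bbr_0417, Bbr_0420, Bbr_0422, Bbr_0526, Bbr_1551 and Bbr_1552 rest on a ribose signal at background.

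Tested as sets with camera, the gal and gos clusters stood above the other genes at a preset correlation between genes (adjusted p = 5.73e-24 for gal and 1.61e-15 for gos). Without the genes that share probes, the camera p at that correlation was 2.25e-19 for gal and 1.68e-09 for gos. With an estimated correlation the adjusted p was 0.144 for both lists, so that neither call held. That version of camera tests with the 1 residual degree of freedom of 2 arrays, so it had little power and decides nothing. The estimated correlation, 1 for gal and -0.2 for gos, is also poorly determined. The rank version of camera in limma, run at the preset correlation of 0.01, gave an adjusted p of 7.64e-05 for gal and 0.000188 for gos. It therefore does not settle the question of the correlation. The median log2 ratio was 3.29 in the gal cluster and 2.50 in the gos cluster. The lac cluster, with 2 genes, was too small for a set test. The study characterised these clusters on these samples, so that their direction, their counts adjusted over the list alone and these set tests are not independent evidence.

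Outside these clusters 92 further genes rose. The files do not pair locus tags with gene names, so only the leading genes of each direction are given by tag. Bbr_0491 had a log2 ratio of 1.71 ± 0.19 (SD), or 3.26-fold (adjusted p = 4.20e-12). Bbr_1719 had one of 1.60 ± 0.48, or 3.03-fold (adjusted p = 1.91e-10), and was well above background on ribose on 1 of 2 arrays. The log2 ratio of Bbr_1719 was 1.26 on replicate 2 alone, and it moved to 1.16 without background correction and to 3.32 with the deposited log ratios.

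Among the genes that fell, Bbr_1417 had a mean log2 ratio of -6.81 ± 1.48 (SD, adjusted p = 1.20e-19), with -7.85 on replicate 1 and -5.76 on replicate 2. Next to it, Bbr_1418 had one of -6.63 ± 1.09 (adjusted p = 1.33e-21). Both belong to the run of 5 tags, and both were well above background on GOS on 1 of 2 arrays, so that the size of their change is uncertain and they have no firm order. With an intensity trend and a robust prior in the variance model, only 2 of the 5 genes of the run passed, and neither Bbr_1417 (adjusted p = 0.137) nor Bbr_1418 (adjusted p = 0.0958) did, although the ratio itself was lower on both arrays. Their arrays differed more than those of most genes, for which the median SD was 0.11.

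**Figure D3:**
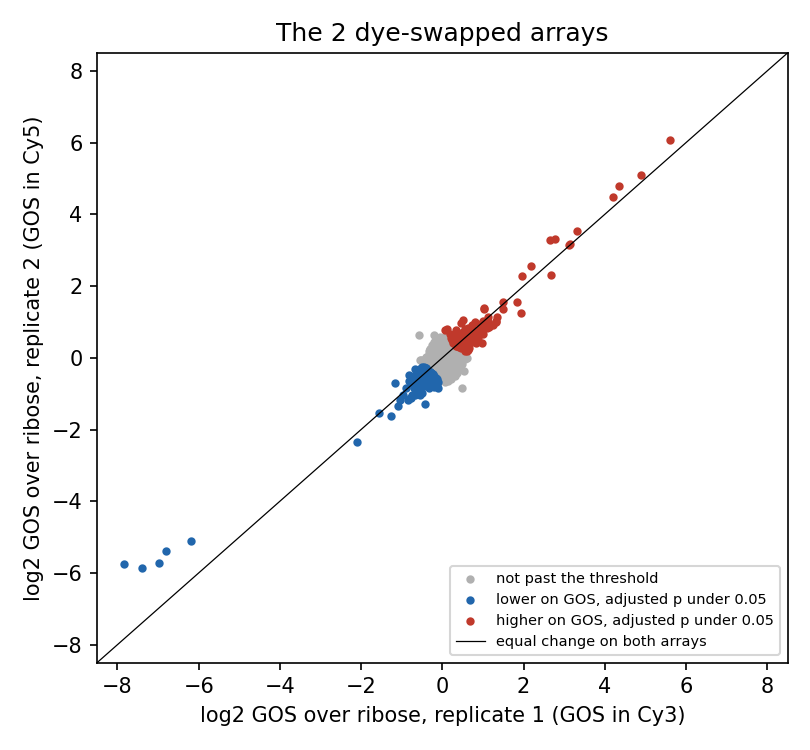
Log2 ratio of GOS over ribose of each tested gene on replicate 1 (horizontal axis, GOS in Cy3) and on replicate 2 (vertical axis, GOS in Cy5), with the line of equal change. The arrays correlated at r = 0.906, and the 5 genes with the lowest ratios lie above the line, with larger changes on replicate 1.

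The criterion stated for the study was a Cyber-T p under 0.001 together with a ratio over 3 or under 0.33. With a Cyber-T test set up here, 20 genes met it, 14 of them higher and 6 lower on GOS. Of the 14, 12 were members of the 3 clusters and the other two were Bbr_0491 and Bbr_1719. Without the genes that share probes, 16 genes met the criterion. Of the 6 that were lower, 5 made up the run with Bbr_1417 and Bbr_1418, and 1 lay elsewhere. With that trend and prior in place of Cyber-T, all 14 higher genes met the criterion but 2 of the 6 lower ones did, 1 of them in the run. The ratio alone, without a test, was met by the same number, 20 genes. This count was 45 with the scanner software's processed signals.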

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

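The chromosomal features were the main measurement, and 24 features outside them were not tested. Of these, only the one named CDS in the files was well above background with all 3 probes in both channels on both arrays. Its mean log2 signal was 10.10, against 7.36 for the negative control spots. The other features, among them 7 spike and 15 plasmid features, lay between 6.17 and 7.28. The CDS feature had a log2 ratio of 0.24 ± 0.06 (SD, n = 2) and was not tested. Its name does not tell which gene it belongs to.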

How the results depend on the processing

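All 236 calls kept their sign under every alternative in which the gene was measured. In settings that change only the test or the set of genes the log ratios stay as they are. There the sign could not change, and only the side of the threshold could move. Aquantile normalization leaves both the log ratios and the calls as they are and is not counted. Of 214 other values of the 15 named genes under alternatives, 212 kept their direction and, where tested, their side of the threshold; genes at background on 1 sugar had no value under the strict filter. The 2 others were those of Bbr_1417 and Bbr_1418, which did not pass with an intensity trend and robust prior (adjusted p = 0.137 and 0.0958). With that setting 2 of the 5 genes of their run passed, and 16 genes met the criterion in place of 20.

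Against 105 genes higher and 131 lower, scanner processed signals gave 68 and 71, of which 129 were among the 236. There were 82 higher and 87 lower without background correction, 89 and 88 with the median of the probes, 93 and 81 with the brightest probe, and 74 and 60 with Cyber-T. With the last 3 settings more genes were higher than lower. Median centring in place of loess moved the split to 77 higher and 170 lower, 31.2% higher in place of 44.5%, with 203 calls shared. Against 20 genes past the study's criterion and 20 past its ratio alone, processed signals gave 44 and 45, the deposited log ratios 44 for both, and the filter for detection on both sugars on both arrays 8 and 8. That filter removes genes at background on 1 sugar by construction; for the other settings the cause was not tested. Each array alone gave 19 to 20 genes past the ratio. With an estimated correlation the camera p was 0.144 for gal and 0.0770 for gos. Leaving out genes with shared probes, chosen after seeing the data, left 102 higher, 133 lower and 16 past the criterion.

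Signal over background limits the size of the folds: log2 ratios of Bbr_0417 ranged from 5.05 without background correction to 8.16 with the deposited log ratios. Those of Bbr_1417 ranged from -5.87 without background correction to -7.93 with processed signals. Its value of -5.76 on replicate 2 alone, under the main processing, reflects the difference between the arrays. The limma adjusted p of Bbr_0417 was 5.98e-24 in the main run, 1.89e-05 with processed signals and 2.79e-76 with an intensity trend and robust prior. The size of such a p is thus no measure of the strength of a change.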

Other observations

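Of 10 tested tRNA features, a list chosen after the data had been seen, 4 rose on GOS and 6 did not pass the test. All 10 had mean ratios above 0, with a median log2 ratio of 0.32. The same held for all 10 under each background correction, scaling and probe summary, which reuse the same 2 arrays. Without the filter on dim genes it held for 20 of 20, but the sign says little for dim features. The plasmid, spike and unplaced features other than CDS, with mean signals below the negative controls, all had mean log2 ratios above 0 too (0.004 to 0.10). Fewer tRNA features passed under some alternatives, namely 2 without background correction, 3 with processed signals, 3 with Cyber-T, and 2 of the 8 kept by the strict filter. In limma, those that rose were tRNA-His at 0.58 ± 0.14 (SD), tRNA-Leu at 0.51 ± 0.23, tRNA-Asn at 0.43 ± 0.27 and tRNA-Cys at 0.42 ± 0.16. The camera p of the list was 0.000625, but 0.173 with an estimated correlation, a version that tests with 1 degree of freedom and so cannot decide. The 16S rRNA feature was not well above background in either channel on either array.

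Beyond the run with Bbr_1417 and Bbr_1418, the locus tags that follow it were lower on GOS as well. Of the 16 tested genes with the next higher tags, 11 fell, with a median log2 ratio of -0.60. The first 8 of them had a median of -1.06 and the last 8 one of -0.24. Of the 16 tested genes with the next lower tags, 4 fell, with a median of -0.04. After the gal, gos and lac clusters, 1, 2 and 1 of 16 genes were higher on GOS, and before them 4, 0 and 2 of 16. This pattern was noticed in the data and no explanation of it was tested.

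Of the tests reported in the next 3 paragraphs, those on dye and on the strength of the response were chosen only after the result was seen; those on spot placement and shared sequence were set before.

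Genes with neighbouring locus tags changed together. In 17 runs of at least 3 consecutive tags every gene was called in the same direction, 8 of them higher and 9 lower, and the runs held 71 genes, 58 of them outside the 3 clusters. Among 10000 shuffles of the calls over the tested genes the highest number of genes in runs was 23 (permutation p = 0.0001, the smallest they can give). Placement of spots on the slide was argued against, since neighbours lay 0.999 times as far apart as random pairs. So was probe sequence shared by neighbours, since 0% of the 1066 neighbouring pairs shared a stretch of 30 identical bases. Across pairs of genes both under 3-fold the correlation was 0.432, with genes not being independent replicates. Neighbours also correlated at 0.260 in the difference between the arrays, which holds dye and replicate effects, so that neighbours share more than the sugar effect. A candidate explanation is transcription as shared units, a hypothesis that the files, which hold no gene strands, leave untested.

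Dye bias as the source of the calls was argued against by the design, since a dye effect equal on both arrays cancels in their mean. Before turning, the Cy5 over Cy3 log2 ratios of the arrays correlated at -0.697 over the 1299 genes under 3-fold. A bias of the dyes would give a correlation above 0. That value is the correlation after turning with its sign reversed, and so no separate evidence. Averaged without turning, the arrays gave 0 calls in limma and 0 in Cyber-T, with 2 genes at an unadjusted p under 0.05. That count says little by itself, because the sugar effect then sits in the residual.

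The largest changes were unequal on the arrays. Of the 20 genes past the study's ratio, 16 changed more on the array that had the more abundant RNA in Cy5, a share of 0.8, namely 11 of 14 that rose and 5 of 6 that fell. A dye-dependent range may thus account for part of the spread of Bbr_1417 and Bbr_1418. The lowest log2 signal of a detected probe was 7.68 in Cy3 and 7.91 in Cy5 for GOS, and 7.48 in Cy3 and 7.77 in Cy5 for ribose. A stronger response of the cultures of 1 replicate throughout would enlarge rises and falls on the same array, whereas 0.167 of the genes that fell and 0.786 of those that rose changed more on replicate 2. Genes of a cluster are not independent, and with 1 array per orientation a difference between replicates that runs opposite ways in the clusters and in the run stays open.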
